A study of Bos taurus with 20 samples.

How the data were processed

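Total RNA from Musculus longissimus dorsi of 20 crossbred bulls, 10 with high and 10 with low intramuscular fat (IMF), was measured on an Affymetrix GeneChip for cattle, with 1 array per animal. Per the labels' protocols, RNA was isolated with TRI Reagent, treated with DNase I, cleaned on RNeasy columns and turned into biotin-labelled cRNA from 0.5 ug of total RNA. Per the submitters' processing notes, the arrays were processed with GCOS 1.1.1 and Affymetrix Expression Console 1.1. The method that summarised the probes of a probe set is not given in the sources used here. The values the authors deposited are linear intensities per probe set, read as such from the table itself, which runs from 0 upwards without any value below it. No detection call was used here, so a dim probe set could be left out only by its mean.

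The deposited table held 24128 probe sets, of which 112 were array controls and were removed. The intensities were taken as log2(value + 1), and the normalization between arrays was kept as the authors deposited it. Fold changes are on this scale and understate the change of dim probe sets. Of the 24016 remaining probe sets, the 40% with the lowest mean over all 20 arrays were left out, and 14409 were tested. The platform annotation gave 1 gene symbol for 13318 of all probe sets, several for 86 and none for 10724, and no gene was named from a probe set with several. The gene identifiers of 13283 probe sets matched the NCBI RefSeq gene table for cattle, and 0 symbols changed by this match. No genome build is stated for the deposited table, so no coordinates are printed.

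High and low IMF were compared for each probe set with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, and p-values were adjusted with the Benjamini-Hochberg method at 0.05. The submitters' series text names a paired t-test. The labels pair no animals, so the fit was unpaired. An unpaired t-test was run as an alternative. The test, the samples in it, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined, except those named below as added. The rule named, per direction, the 8 genes with the smallest limma p, then the 3 tested genes with the smallest p in each of 7 core lists, and the 2 with the smallest p in every other list whose test passed. Most genes outside this rule are marked in the text as chosen after their values were seen. Those without a mark are genes listed for passing adjusted over a list alone, liver genes, and genes with a gap between animals.

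Each of 27 gene lists, written from general knowledge of muscle and fat tissue, was compared with all other genes by limma's camera with a preset correlation between genes of 0.01, on the probe set with the highest mean for each of 7016 genes. A list needed at least 5 tested genes, and 26 lists qualified. The red blood cell list had 3 tested genes and was not tested. Camera was also run with the correlation estimated from these arrays, but not within a title series alone, and limma's fry was run as another test. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. For each animal the mean log2 value over a list was taken as its level, and levels were compared by two-sided permutation tests with 100000 resamples, or by exact permutation tests over all 252 splits for 5 animals against 5.

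The titles hold animal numbers of 2 kinds, 10 with an S before the number and 10 without, with 5 high and 5 low IMF animals in each. The labels do not say what the S stands for. These sets are called the title series here. They were treated as a possible batch, with the title series as a covariate, with each series fitted alone, and with an interaction of IMF group and title series. Permutations with title series in the model kept the number of high IMF animals within each series. Added after the data were seen were the fits without 4 arrays with an albumin signal over 2000, camera with both the title series and an estimated correlation, and the adipocyte level without RBP4 and PCK1, which liver also expresses, with and without the level of liver transcripts as a covariate.

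The same limma code was tested on simulated data for high against low IMF, with the real means and spreads of 14409 probe sets and known changes of 3 sizes in 66 or 67 probe sets each. Without a covariate it recovered 34.8% of changes of 0.5 log2 units, 79.1% of changes of 1 unit and 97.0% of changes of 2 units, with 1 false call. With the title series in the model it recovered 66.7%, 97.0% and 97.0%, with 8 false calls. The simulation kept the differences between title series, gave all animals the same spread for a probe set and varied genes independently, unlike the real arrays. In a simulated set with the adipocyte list raised by 0.3 log2 units, camera called that list and 0 of the others. The median signal of the arrays ran from 51.6 to 67.6, and between 0.462% and 1.05% of the values of an array were 0. The number of arrays limits the precision of all values.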

Results

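Gene expression was profiled in Musculus longissimus dorsi, the long muscle along the back, of 20 bulls of the F2 generation of a cross between Holstein, a dairy breed, and Charolais, a beef breed. The comparison asks how expression differs between muscle with high and with low intramuscular fat (IMF), the fat deposited between muscle fibres. Each group held 10 bulls with 1 array each, and each array carried its own animal number. In each group 5 animals had a title number with an S and 5 without, and the log2 differences of named genes within these title series are given beside the pooled ones, as S and others. The median signal of the 20 arrays lay between 51.6 and 67.6.

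High IMF muscle had higher values of genes that make and store fat. THRSP, which promotes fatty acid synthesis, averaged 8.16 ± 1.90 log2 units in high IMF and 5.71 ± 1.57 in low IMF (SD, n = 10 each), a difference of 2.45 (SE 0.71) or 5.47-fold. CIDEC, a protein of the fat cell lipid droplet, was 3.84-fold higher (log2 difference 1.94, SE 0.67) and FABP4, the fatty acid binding protein of fat cells, 3.14-fold higher (1.65, SE 0.65). For each of these 3 genes all 10 high IMF animals lay above the median of the low IMF animals. SCD, which makes monounsaturated fatty acids, was 2.05-fold higher (1.04, SE 0.37), above that median in 8 of 10. The difference in THRSP was 2.91 log2 units among the S animals and 2.0 among the others. It was 2.16 and 1.72 in CIDEC, 1.99 and 1.32 in FABP4, and 1.57 and 0.50 in SCD. Of 4 arrays with a high albumin signal, 3 were of high IMF, all of them S animals. Without these 4 arrays and with the title series in the model, the differences were 1.70, 1.40, 1.07 and 0.61. None of these genes passed limma's test over all probe sets, where the lowest adjusted p was 0.9997. With the title series in the model the lowest was 0.4505.

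**Figure D1:**
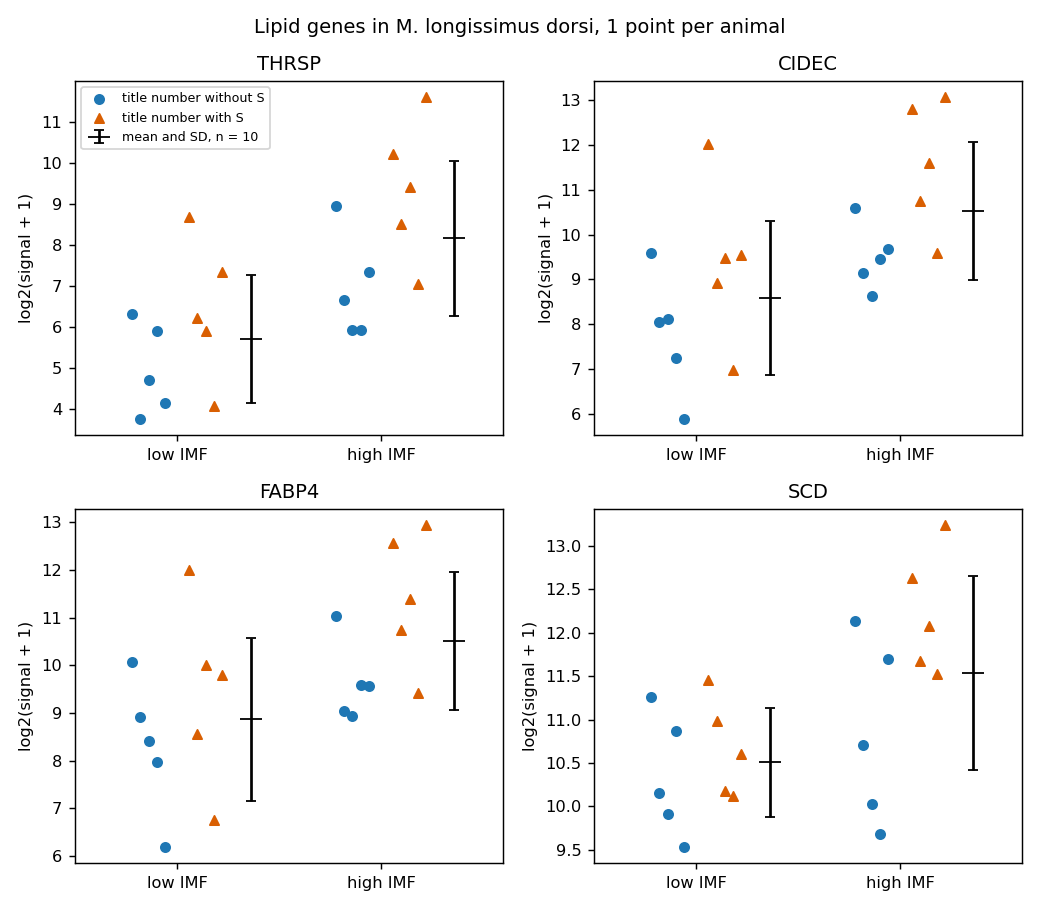
Log2(signal + 1) of THRSP, CIDEC, FABP4 and SCD in each of 20 bulls by IMF group, with circles for title numbers without S, triangles for those with S, and bars for the mean and SD of each group (n = 10). THRSP averaged 8.16 in high and 5.71 in low IMF, and the ranges of the groups overlapped for each gene.

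As a group, the adipocyte markers rose in high IMF by camera (adjusted p = 2.65e-08), with 12 of 15 tested genes higher and a median log2 difference of 0.49. The call was lost with an estimated correlation between genes (adjusted p = 0.259 with an estimated correlation). TRARG1, a protein of glucose transporter vesicles, was 2.15-fold higher (SE 0.53 log2 units, S 1.69, others 0.51). PCK1, which supplies glycerol for triglycerides in fat cells, differed by 1.24 (SE 0.62, S 2.03, others 0.46) and CFD, the secreted protease adipsin, by -0.22 (SE 0.23, S -0.15, others -0.28). These 3 genes were chosen after their values were seen. Adjusted over the list alone, 1 gene passed, THRSP with adjusted p = 0.0366, against 0 adjusted over all probe sets. With the title series in the model, 5 passed adjusted over the list alone, THRSP, CIDEC, FABP4, TRARG1 and CIDEA, with adjusted p from 0.00631 to 0.0402. Over all probe sets 0 passed in that fit. Adjustment over a list alone does not allow for the other lists tested. The median difference was 0.60 in the S animals (camera adjusted p = 2.69e-09) and 0.21 in the others (0.0381). Without the 4 arrays with a high albumin signal and with the title series in the model it was 0.23 (camera adjusted p = 0.00197).

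The genes of lipogenesis and triglyceride synthesis rose in high IMF by camera (adjusted p = 9.37e-10), with 19 of 22 higher and a median log2 difference of 0.30. This call also was lost with an estimated correlation (adjusted p = 0.259 with an estimated correlation). ACLY, which makes cytosolic acetyl-CoA, differed by 0.55 (SE 0.24, S 0.84, others 0.26), or 0.31 without the 4 arrays with a high albumin signal, DGAT2, which completes triglycerides, by 1.01 (SE 0.45, S 1.35, others 0.67), and FASN, the fatty acid synthase, by 0.74 (SE 0.42, S 0.96, others 0.52), the last 2 chosen after their values were seen. Adjusted over the list alone, 0 genes passed limma's test, as over all probe sets, and 4 had an unadjusted p under 0.05. With the title series in the model, 7 passed adjusted over the list alone: THRSP, SCD, ACLY, DGAT2, ACSS2, AGPAT2 and PGD. Over all probe sets 0 passed in that limma fit, with THRSP at an adjusted p of 0.505 and SCD and ACLY at 0.676. The median difference was 0.35 in the S animals and 0.19 in the others (camera adjusted p = 0.00671).

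The genes of lipolysis and lipid droplet proteins rose by camera (adjusted p = 6.92e-04; 0.378 with an estimated correlation), with 8 of 12 higher and a median log2 difference of 0.18. CIDEC and FITM2, which helps lipid droplets form (0.21, SE 0.11, S 0.25, others 0.18), had the smallest p. CIDEC and CIDEA, among others, are adipocyte markers too, and THRSP is in both the adipocyte and the lipogenesis lists. The calls of these lists are therefore not independent. PLIN5, a droplet coat protein, and PNPLA2, the main triglyceride lipase, both chosen after their values were seen, differed by -0.27 (S -0.54, others -0.0059) and -0.09 (S -0.26, others 0.07). The median was 0.19 in the S animals and 0.16 in the others. Adjusted over the list alone, 0 genes passed, and 1 (CIDEC) with the title series in the model. The genes of cholesterol synthesis rose as well (adjusted p = 6.92e-04; 0.354 with an estimated correlation), with 11 of 14 higher and a median of 0.09, 0.12 in the S animals (camera adjusted p = 0.00129) and 0.08 in the others, where the list did not pass (0.336). INSIG1, a brake on sterol synthesis that is induced together with it, differed by 0.73 (SE 0.29, S 0.97, others 0.49), and SREBF2, its main transcription factor, by 0.31 (SE 0.17, S 0.29, others 0.34). A dimmer SREBF2 probe set, left out of the tests, differed by -0.02. Adjusted over the cholesterol list alone, 0 genes passed, and 1 (SREBF2, adjusted p = 0.0440) with the title series in the model. Neither CIDEC nor SREBF2 passed over all probe sets in that fit. Fatty acid uptake and transport (8 genes, adjusted p = 0.622) pointed higher in the test with a median of -0.02 and a mean of 0.14. Preadipocyte and adipogenic regulators (17 genes, 0.900) did not pass either and turned to lower after quantile normalization. Without the 4 arrays with a high albumin signal and with the title series in the model, the lipolysis list was no longer past the threshold (adjusted p = 0.121, median 0.07).

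Averaged over its 15 tested genes, the adipocyte marker level was 8.72 ± 0.81 log2 units in high IMF and 8.01 ± 0.64 in low IMF (SD, n = 10 each). The difference of 0.71 had a permutation p of 0.0439, and 0.0117 when animals were permuted within title series. It was 0.96 among the S animals (exact permutation p = 0.0635, 5 against 5) and 0.45 among the others (exact permutation p = 0.103). The S animals themselves had a level 0.93 log2 units above the others (permutation p = 0.00497). Without the 4 arrays with a high albumin signal and with the title series in the model, the difference was 0.46 (permutation p = 0.0804), and without high IMF replicate 10 it was 0.54 (permutation p = 0.0877).

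**Figure D2:**
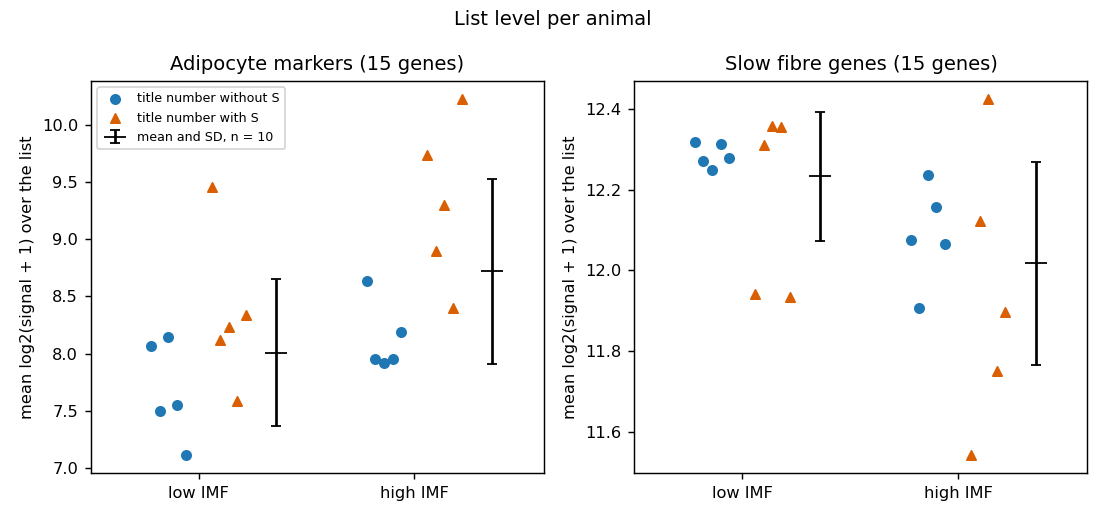
Mean log2(signal + 1) over 15 adipocyte markers (left) and 15 slow fibre genes (right) in each of 20 bulls by IMF group, with circles for title numbers without S, triangles for those with S, and bars for the mean and SD (n = 10). The adipocyte level averaged 8.72 in high and 8.01 in low IMF, and the slow fibre level 12.02 and 12.23.

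Slow fibre genes had lower values on average in high IMF, in part on dim arrays. The list fell by camera (adjusted p = 6.92e-04; 0.393 with an estimated correlation), with 13 of 15 lower and a median log2 difference of -0.10. The median of all log2 differences was -0.03 on the deposited scaling. Counts of lower genes in a list, here and below, include this shift. TNNT1, the slow troponin T, differed by -0.19 (SE 0.09, S -0.26, others -0.13) and was below the low IMF median in 9 of 10 high IMF animals. PLN, which restrains the calcium pump of slow fibres, differed by -0.74 (SE 0.37, S -1.15, others -0.34), and its other 2 probe sets by -0.74 and -0.76. MYL6B, a slow myosin light chain, differed by -0.70 (SE 0.37), with -1.44 in the animals without S and 0.04 in those with S. Without the 4 arrays with a high albumin signal and with the title series in the model, MYL6B differed by -1.07 (SE 0.38). One of these arrays, high IMF replicate 8, had the highest MYL6B value of its group, at 10.68. MYH7, the slow myosin heavy chain, chosen after its value was seen, differed by -0.10 (SE 0.08, S -0.17, others -0.02). Adjusted over the list alone, 0 genes passed. The list median was -0.12 in the S animals (camera adjusted p = 0.253) and -0.05 in the others (0.00617). High IMF replicates 6 and 9, both S arrays, had the lowest slow fibre levels of all arrays, 11.54 and 11.75. They also had the lowest median signals, 51.6 and 56.6. Without replicate 6 PLN differed by -0.57 and TNNT1 by -0.15. With arrays centred on their medians the list still fell by camera (adjusted p = 0.00138, median -0.06). A fit without both arrays was not run.

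Fast fibre genes did not pass (adjusted p = 0.934, 12 genes, median -0.01, and -0.02 in each title series), and with arrays centred on their medians the list turned to higher (adjusted p = 0.666). ATP1B1, a sodium pump subunit, TPM1, a tropomyosin, and MYOZ1, a Z-disc protein, differed by -0.20 (S -0.21, others -0.19), 0.12 (S 0.10, others 0.14) and -0.04 (S -0.09, others 0.0097), while the second TPM1 probe set differed by -0.17. Oxidative phosphorylation genes had lower values in 45 of 55 (median -0.04, S -0.08, others -0.0070) and did not pass (adjusted p = 0.233). With arrays centred on their medians the median was 0.0037 (adjusted p = 0.739). NDUFA5 differed by 0.10 on the probe set used (S 0.08, others 0.12) and by -0.15 and -0.09 on 2 more, ATP5F1B by -0.09 (S -0.15, others -0.02) and ATP5PD by -0.09 (S -0.10, others -0.07). Mitochondrial fatty acid oxidation (26 genes, adjusted p = 0.490) pointed higher with a median of 0.0057 (S -0.04, others 0.04) and a mean of -0.02. Among its genes SLC25A20, the carnitine carrier, differed by 0.13 (S 0.01, others 0.24), HADHB by 0.16 (S 0.0083, others 0.30), and PPARGC1A, a coactivator of mitochondrial genes, by -0.43 (SE 0.34). In PPARGC1A the difference was -0.87 in the S animals and 0.0096 in the others. The TCA cycle (15 genes, adjusted p = 0.666, median -0.05, S -0.13, others 0.03) and glycolysis and glycogen (20 genes, 0.936, median -0.03, S -0.05, others -0.0038) did not pass, and the glycolysis list turned to higher under both other scalings. Adjusted over each of these lists alone, 0 genes passed.

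Extracellular matrix and fibroblast genes rose by camera (adjusted p = 4.14e-05; 0.496 with an estimated correlation), with 24 of 27 higher and a median log2 difference of 0.17. LUM, a collagen-binding proteoglycan, differed by 0.38 (SE 0.24, S 0.49, others 0.26), and COL3A1, chosen after its value was seen, by 0.31 (SE 0.21, S 0.53, others 0.09). TNC, a matrix glycoprotein, differed by 0.23 on the probe set used (S 0.17, others 0.29) and by -0.09 on its second, and COL6A2 by -0.14 (S -0.10, others -0.17) and 0.14. The matrix level differed by 0.15 log2 units over all animals (permutation p = 0.415). Within a title series camera was run with the preset correlation alone. The list median was 0.33 in the S animals (camera adjusted p = 4.29e-15) and -0.04 in the others, where the list pointed lower (0.820). By the camera test of that difference, the shift was larger in the S animals (adjusted p = 8.81e-08; 0.630 with an estimated correlation). Adjusted over the list alone, 0 genes passed.

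Endothelial cell markers fell by camera (adjusted p = 0.0328; 0.639 with an estimated correlation), with 10 of 10 lower and a median of -0.13, among them PECAM1 (-0.21, SE 0.14, S -0.27, others -0.15) and ERG, an endothelial transcription factor (-0.24, SE 0.18, S -0.52, others 0.04). The median was -0.27 in the S animals (camera adjusted p = 0.00999) and 0.04 in the others (0.976), and with the title series in the model the list no longer passed (adjusted p = 0.0903). Markers of pericytes and smooth muscle (adjusted p = 0.233), macrophages (0.233), lymphocytes (0.938), nerve and Schwann cells (0.818) and satellite cells and myogenic regulators (0.758) did not pass, nor did the interferon response (0.233). Among macrophage markers 6 of 7 had lower values in high IMF, with a median of -0.20. In the S animals this list pointed higher (adjusted p = 0.930, median -0.05), and in the others it passed as lower by camera (0.0440, median -0.29). With an estimated correlation the adjusted p was 0.809 for all animals, and it was not run for a title series alone. Camera did not call the difference between the series (0.0768). Adjusted over each of these lists alone, 0 genes passed.

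Proteasome subunits rose by camera (adjusted p = 0.0140; 0.393 with an estimated correlation), with 19 of 26 higher and a median of 0.04, and cytosolic ribosomal proteins fell (adjusted p = 0.0196; 0.882 with an estimated correlation), with 53 of 62 lower and a median of -0.05. PSMB6 differed by 0.11 (SE 0.08, S 0.07, others 0.14) and PSMA4 by -0.22 (SE 0.14, S -0.16, others -0.29), against the direction of the proteasome list. RPS2 differed by -0.15 (SE 0.08, S -0.20, others -0.10) and RPL37 by 0.40 (SE 0.18, S 0.65, others 0.15), on a dim probe set and against the direction of the ribosomal list. The median of all log2 differences was -0.03, and after quantile normalization neither list passed (adjusted p = 0.0991 and 0.397). With arrays centred on their medians the proteasome list passed (0.00586) and the ribosomal list did not (0.475). The proteasome median was 0.0054 in the S animals (camera adjusted p = 0.163) and 0.09 in the others (0.0381). The ribosomal median was -0.05 in both, with the test pointing higher in the S animals (0.722) and lower in the others (1.99e-05). Muscle protein breakdown and atrophy (adjusted p = 0.233), insulin signalling (0.643), circadian clock genes (0.900) and immediate early and heat shock genes (0.643) did not pass. In the S animals alone, muscle protein breakdown passed as lower by camera (0.0257), with a median of -0.18 against 0.02 in the others (0.998). With an estimated correlation its adjusted p was 0.393 for all animals. The tests of the circadian, immediate early and nerve lists pointed higher, while their medians were -0.05, -0.0015 and -0.0030.

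**Figure D3:**
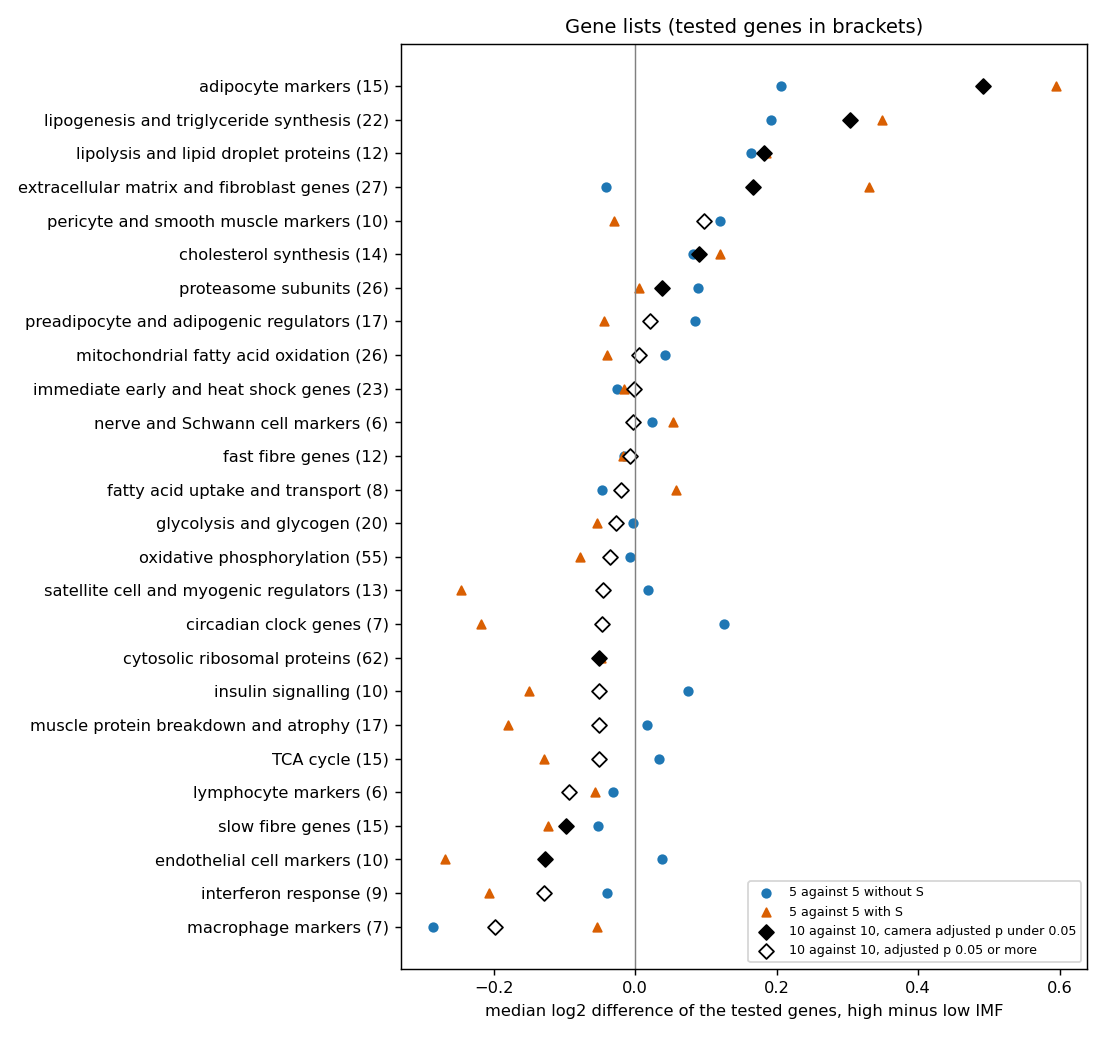
Median log2 difference (high minus low IMF) of the tested genes of 26 lists, with diamonds for 10 against 10 animals (black where the camera adjusted p was under 0.05 with the preset correlation), triangles for the S animals and circles for those without S (5 against 5 each). The adipocyte markers lie farthest to the right, at 0.49, and the extracellular matrix list lies at 0.33 in the S animals and at -0.04 in the others.

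Outside these lists, the smallest p among lower values in high IMF belonged to GNAS, the stimulatory G protein alpha subunit (-0.45, SE 0.12, S -0.53, others -0.36), and SOCS2, an inhibitor of growth hormone signalling (-0.95, SE 0.26, 0.519-fold). SOCS2 lay below the low IMF median in 10 of 10 high IMF animals, with a difference of -1.31 in the S animals and -0.59 in the others. The 2 brighter probe sets of GNAS differed by 0.06 and -0.07. PIAS1 (-0.39, S -0.47, others -0.30), the transcription factor POU2F1 (-0.38, S -0.45, others -0.30) and the DNA repair nuclease FEN1 (-0.30, S -0.40, others -0.21) followed. After them came the amino acid transporter SLC43A2 (-0.69, S -0.77, others -0.61), the linker histone H1-2 (-0.65, S -0.84, others -0.46) and LOC510377 (-0.32, S -0.17, others -0.48, and -0.09 on its second tested probe set). Among higher values came NCALD (0.34, S 0.47, others 0.20), the small GTPase MRAS (0.40, S 0.41, others 0.40), BLCAP (0.29, S 0.27, others 0.31), SMAD5, a mediator of BMP signalling (0.28, S 0.42, others 0.14), and PPT2 (0.27, S 0.33, others 0.21). The second tested probe sets of NCALD, MRAS, BLCAP and PPT2 differed by 0.40, 0.16, 0.09 and -0.0029. None of these passed limma's test over all probe sets.

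Over all 14409 probe sets, limma called 0 higher and 0 lower in high IMF, and the unpaired t-test also called 0. At an unadjusted p under 0.05 limma counted 91 higher and 148 lower, 239 in all, where chance gives 720, and the t-test 258. The pooled fit left the difference between title series in its residual spread, which makes its p-values larger. A count under 720 is therefore no sign of less difference than chance. With the title series in the model the counts were 0 calls and 1057 at an unadjusted p under 0.05 (293 higher, 764 lower). The lowest adjusted p of that limma fit was 0.4505. Of 100 random splits within title series, 10 gave as many as 1057, with a median of 560. The balance was opposite in the title series, with 196 higher and 945 lower in the S animals alone and 371 higher and 142 lower in the others, and 0 calls in each. Quantile normalization turned the pooled split of the unadjusted count to 158 higher and 114 lower, and centring arrays on their medians to 151 and 110. The splits within a title series are given on the deposited scaling alone. High IMF replicates 6 and 9, both S arrays, had the lowest median signals of all arrays, 51.6 and 56.6. Whether the opposite balance goes beyond a shift of whole arrays was not tested. Of the 26 lists, camera called 6 higher and 3 lower with the preset correlation, 0 with an estimated correlation, and fry called 0. Of 100 random splits of the animals, 6 gave as many lists with the preset correlation, and the median was 4. After Benjamini-Hochberg adjustment of the permutation tests on list levels, 0 lists passed, pooled or within title series.

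The title series differed far more than the IMF groups. The first principal component held 53.0% of the variance and separated the 10 S arrays from the 10 others. With IMF group in the model, limma called 4818 probe sets higher and 5020 lower in the S arrays. THRSP was 1.94 log2 units higher in the S arrays, and CIDEC 1.84 higher, while PLN differed by -1.28 and PPARGC1A by -1.16. The median correlation between arrays was 0.971 within and 0.916 between title series. The 9 bacterial hybridisation controls, which are added to every array in fixed amounts, were lower in the S arrays by 0.63 log2 units on average (permutation p = 3e-05), while the difference between IMF groups was -0.0063 (permutation p = 0.967).

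**Figure D4:**
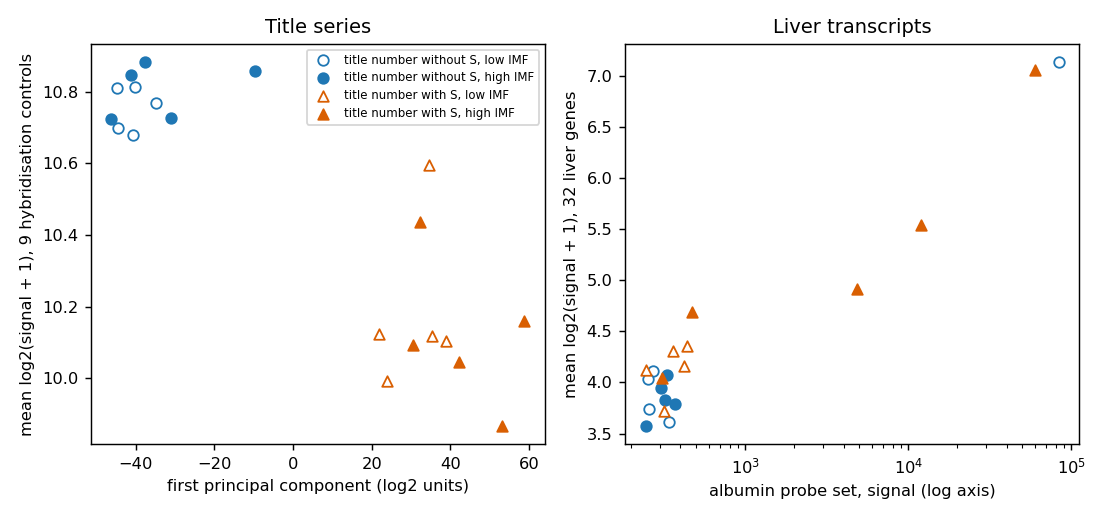
Left, mean log2(signal + 1) of 9 hybridisation controls against the first principal component, and right, mean log2(signal + 1) of 32 liver genes against the albumin signal on a log axis, 1 point per array, with circles for title numbers without S, triangles for those with S, open symbols for low IMF and filled ones for high IMF. The title series lie apart on the left, and 4 arrays with albumin signals from 4871 to 83307 stand apart on the right.

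A further comparison asked whether the IMF difference was the same in both title series. For the interaction of IMF group and title series limma called 0 probe sets, with 769 at an unadjusted p under 0.05 where chance gives 720. Of these, 125 had a higher and 644 a lower IMF difference in the S animals. This split is given on the deposited scaling alone, and a shift of a whole array enters it. The whole count was 495 after quantile normalization and 595 with arrays centred on their medians, both below 720. Among the 42 named genes the lowest adjusted p of the interaction was 0.866 adjusted over all probe sets and 0.621 adjusted over these genes alone. By camera the shift was larger in the S animals for adipocyte markers (adjusted p = 3.29e-05; 0.630 with an estimated correlation) and lipogenesis and triglyceride synthesis (0.00313; 0.630 with an estimated correlation), beside the matrix list. Ribosomal proteins lay higher in the S animals relative to other genes (0.00194, or 0.750 with an estimated correlation). Their own median difference was -0.05 in both title series. Of the 5 high IMF S arrays, 3 had a high albumin signal, and these 3 had the highest adipocyte levels of their group. The list interactions are not given without those arrays, so a larger shift in the S animals cannot be told apart from them. At the level of each animal, the interaction did not pass a permutation test for the adipocyte (adjusted p = 0.747), lipogenesis (0.747), matrix (0.747) or ribosomal (0.946) lists. It passed for muscle protein breakdown and atrophy (-0.24 log2 units, adjusted p = 0.0367) and for circadian clock genes (-0.22, adjusted p = 0.0380). Camera called neither list (adjusted p = 0.110 and 0.463, or 0.630 and 0.636 with an estimated correlation). The levels are not relative to other genes, so a shift of a whole array enters them, and they are given on the deposited scaling alone. High IMF replicates 6 and 9, both S arrays, had the lowest median signals of all arrays, 51.6 and 56.6. Whether the 2 lists differ beyond such a shift was not tested at this level. In the first list EIF4EBP1, a repressor of translation, differed by -0.58 in the S animals and 0.02 in the others, and in the second NR1D1, a clock repressor, by -0.42 and 0.30. Both genes were chosen after their values were seen.

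Albumin, the main plasma protein made by liver, had a high signal on 4 of the 20 arrays, 3 of high and 1 of low IMF. Its gene ALB read 83307 in low IMF replicate 3, 59753 in high IMF replicate 10, 11889 in high IMF replicate 8 and 4871 in high IMF replicate 6, against a median of 320 and a maximum of 469 on the other 16 arrays. Of 9 probe sets annotated to ALB, 2 were high on each of these 4 arrays, and these values are from the brighter of them. Among other abundant liver transcripts, AHSG, the plasma protein fetuin-A, was at 10652 on low IMF replicate 3 and 8566 on high IMF replicate 10 (median of the 16 arrays 491), and at 451 and 398 on high IMF replicates 8 and 6. APOA2, an apolipoprotein of plasma, was at 5410 and 9936 (median 19.4), and at 1199 and 33.0 on replicates 8 and 6. FGG, a fibrinogen chain, was at 2611 and 780 (median 6.43, maximum 77.8), and at 291 and 110 on replicates 8 and 6. SERPINA1, a plasma protease inhibitor, was at 6378 and 6722 (median 40.7, maximum 55.1), and at 57.3 and 41.7 on replicates 8 and 6, and AMBP, a plasma protein precursor, at 1112 and 926 (maximum 40.8), and at 38.2 and 42.8. Of 32 liver genes without albumin, 26 lay above every array without high albumin of the same title series on low IMF replicate 3. On high IMF replicates 10, 8 and 6 these were 25, 15 and 10, against up to 10 on the other S arrays and up to 6 on the others. High IMF replicates 10, 6 and 8 also had the highest adipocyte levels of their group, at 10.22, 9.73 and 9.30 log2 units. Without these 4 arrays and with the title series in the model, limma called 0 probe sets, with 663 at an unadjusted p under 0.05, and camera called 6 lists. These were adipocyte markers (adjusted p = 0.00197), lipogenesis (2.64e-05), slow fibre genes (0.00530), extracellular matrix (0.0147), cholesterol synthesis (0.00223) and ribosomal proteins (9.86e-07), each in the direction given above. Each of these 6 lists lost its call in all 20 animals with an estimated correlation, with or without the title series in the model, and camera was not run with an estimated correlation on the 16 arrays.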

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

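The tests of liver RNA, of the hybridisation controls and control transcripts, and of the adipocyte markers below were chosen after the patterns had been seen, while the random splits, the fast fibre test and the test of liver level by IMF group were set before their results. In 88 groups of 10 animals tested for a single distant sample, 3 had one, where chance gives about 1 in 20 groups or 4.4. MYL6B in high IMF replicate 8 was 10.68 log2 units, with the nearest animal of its group at 9.15 and the group median at 8.51. The adipocyte marker level of low IMF replicate 6 was 9.45, the nearest was 8.34 and the median 8.09. The liver transcript level of low IMF replicate 3 was 7.13, the nearest was 4.36 and the median 4.12. The IMF difference also differed between title series by permutation, by -0.24 log2 units for muscle protein breakdown and atrophy (adjusted p = 0.0367) and by -0.22 for circadian clock genes (adjusted p = 0.0380). Camera did not call this difference for either list (adjusted p = 0.110 and 0.463, or 0.630 and 0.636 with an estimated correlation). The permutation result is given on the deposited scaling alone, and a shift of a whole array enters the levels it compares.

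For the counts of gene lists, and of probe sets at an unadjusted p under 0.05 with the title series in the model, chance could not be excluded. For probe sets past the threshold limma's real count was 0 (239 at an unadjusted p under 0.05), which no split can undercut, so the 100 of 100 splits as large decide nothing. The highest other count was 4337. That split and the next, with 3887, put 2 S arrays in one group and 8 in the other, which points to the title series as a structure of the samples. With the title series in the model, 10 of 100 splits had as many probe sets at an unadjusted p under 0.05 as the real 1057, and the highest other had 2207. For gene lists past camera's threshold, 6 of 100 splits reached the real 9, with a median of 4 and 15 as the highest other. With the title series in the model 19 of 100 reached the real 8, with a median of 5 and 10 as the highest other. Camera with the preset correlation thus called several lists in a typical random split, so its small p-values overstate the evidence. For the interaction limma called 0 probe sets (769 at an unadjusted p under 0.05), so 100 of 100 splits were as large by construction, and the highest other count was 1.

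Liver transcripts stood out on 4 arrays. In the series without S, low IMF replicate 3 had the highest value of its series for 26 of 32 liver genes other than albumin, and in the S series high IMF replicate 10 had it for 25, or 78.1%. RNA from liver may explain this on those 2 arrays. It stays open for high IMF replicate 8, where 15 of the 32 genes lay above every S array without high albumin, but AHSG, SERPINA1 and AMBP (451, 57.3 and 38.2) were near the other arrays, and for replicate 6, where 10 did so, as on replicate 7, which had no high albumin. Another tissue in place of muscle on the 4 arrays is argued against by the 12 fast fibre genes, whose median difference between these arrays and the rest of their series was 0.0039 log2 units. Whether the liver level went with IMF group stays open, with a difference of 0.21 (95% interval -0.77 to 1.19, permutation p = 0.631 within title series).

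The adipocyte marker level was higher in high IMF. Liver RNA as the whole cause is argued against only as far as the liver level captures it. Without RBP4 and PCK1, which liver expresses too, the difference was 0.67 log2 units (SE 0.22) with the title series in the model and 0.62 (SE 0.20) with the liver level added (permutation p = 0.00809 in both). The other markers stayed in, and whether liver expresses them was not tested. The liver level was 7.13 on low IMF replicate 3 and 7.06 on high IMF replicate 10. On high IMF replicates 8 and 6 it was 5.54 and 4.91, and at most 4.69 on the other arrays, so it adjusts little for those 2. Leaving out the 4 arrays altogether gave 0.46 for all markers (permutation p = 0.0804), so the size depended on which animals were used. More fat cells in high IMF muscle, or larger ones, may account for it but stay untested, since the 12 of 15 markers with a higher mean there are the pattern itself.

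The title series differed in 4818 probe sets that were higher and 5020 that were lower in S, and a hybridisation batch may be part of this. The bacterial hybridisation controls, which do not come from the animals, had a median difference of -0.67 log2 units, S minus no S. They do not test the labelling of the samples, and their values carry the deposited scaling. RNA degradation alone is argued against by the 3' minus 5' values of 6 control transcripts, which moved both ways, from -0.58 to 0.57. A difference between the animals of the series, such as age or herd, stays open as untested, since the labels do not say what the S stands for.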

How the results depend on the processing

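The fits without the 4 albumin arrays, camera with both title series and an estimated correlation, and the adipocyte level without RBP4 and PCK1 were chosen after the data had been seen. No paired analysis was possible because the labels pair no animals. Limma called 0 probe sets for IMF under every alternative run, and 0 for the interaction under those run for it. The interaction count at an unadjusted p under 0.05, 769, was 495 after quantile normalization and 595 with arrays centred on their medians. It was 962 without the 4 albumin arrays. With no filter on dim probe sets it was 1109 and with the lowest 60% left out 623, where more or fewer probe sets were tested.

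The count at an unadjusted p under 0.05, 239, was 524 with no filter on dim probe sets and 139 with the lowest 60% left out, where more or fewer probe sets were tested. It was 1057 with the title series as a covariate, 1141 with S titles only, 513 with titles without S only, 1080 with the adipocyte level as a covariate and 663 without the 4 albumin arrays and with the title series. Without high IMF replicate 6 it was 151, with more higher than lower, against the main split of 91 higher and 148 lower. Without high IMF replicate 4 it was 386 and without high IMF replicate 1 388, both with more lower than higher. The count stayed between 231 and 275 under the other scalings, pseudocounts, limma settings and the t-test. Of these, both scalings and limma with array weights also had more higher than lower.

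Camera's 9 lists became 0 with an estimated correlation, 0 with fry and 0 with title series and an estimated correlation. They numbered 6 to 9 under the other alternatives. With no filter on dim probe sets there were 9, of which 8 were among the main 9, and endothelial markers lost their call (adjusted p = 0.0504). Each title series alone gave 7, of which 6 were among the main 9. Leaving out 1 animal gave 6 to 11 lists. Adipocyte markers, lipogenesis, lipid droplet, slow fibre, matrix and cholesterol lists passed in all 20 of these fits. Ribosomal proteins lost their call in 7 of them (adjusted p up to 0.574), endothelial markers in 8 (up to 0.369) and proteasome subunits in 4 (up to 0.192). Oxidative phosphorylation ranged from 4.41e-04 (without low IMF replicate 2) to 0.984 (without high IMF replicate 1, where it turned to higher), and passed as lower without high IMF replicate 8 (0.00962) and low IMF replicate 6 (0.0238). Fatty acid oxidation ranged from 0.0637 to 0.948 and turned to lower without high IMF replicate 4, and fast fibre genes from 0.753 to 0.998 and to higher without high IMF replicates 5 and 8 and low IMF replicate 5.

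Among the 12 lists that passed or were chosen as core, and the named genes, directions reversed as follows outside the fits without 1 animal, and the cause was not tested. Fast fibre genes pointed higher with arrays centred on their medians (adjusted p = 0.666). With S titles only, ribosomal proteins (0.722) and fast fibre genes (0.722) pointed higher, fatty acid oxidation lower (0.930), and MYL6B was 0.038. With titles without S only, the matrix list pointed lower (0.820), and PPARGC1A, MYOZ1 and ERG were 0.0096, 0.0097 and 0.043. Among the other 14 lists, checked under the scalings, title series and albumin settings alone, with 0 passing in the reversed direction, glycolysis turned under both scalings and preadipocyte regulators under quantile normalization. With the title series as a covariate lymphocyte and circadian lists turned, and with S titles only these and macrophage markers. With titles without S only, fatty acid uptake, TCA cycle, satellite cell, insulin, immediate early and nerve lists turned. Without the 4 albumin arrays, fatty acid uptake, lymphocyte, interferon and immediate early lists turned. The named genes kept their direction under both scalings, both filters and with the title series as a covariate, where tested (36 of 42 with the stricter filter).

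The adipocyte level difference of 0.71 lost its permutation p under 0.05 with S titles only (0.96, exact p = 0.0635), titles without S only (0.45, exact p = 0.103) and without the 4 albumin arrays (0.46, p = 0.0804), where fewer animals were used. Without 1 animal it ranged from 0.54 (without high IMF replicate 10, permutation p = 0.0877) to 0.87 (without low IMF replicate 6, p = 0.00793). The p was above 0.05 in 12 of these 20 (without high IMF replicates 1, 6, 7, 8 and 10, and low IMF replicates 1, 2, 3, 4, 5, 7 and 9). Without detection calls, signal over background could not be judged for single probe sets.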

Other observations

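The search for gaps between animals was chosen after the data had been seen. Across animals of a title series, levels of 25 other lists were set against the adipocyte marker level, 50 relations in all, by two-sided permutation with Benjamini-Hochberg adjustment. In the S animals the lipogenesis level rose with it (r = 0.92, adjusted p = 0.00500, and 0.90 without the 2 farthest animals). In the others r was 0.80 (adjusted p = 0.0947, and 0.53 without the 2 farthest). These lists share genes such as THRSP. A fall of the slow fibre level with more adipocyte transcripts may be present but stays open, with r = -0.48 in the animals without S (adjusted p = 0.523) and -0.50 in the S animals (adjusted p = 0.523). For the matrix and fibroblast level r was 0.49 (adjusted p = 0.523) in the animals without S and 0.75 (adjusted p = 0.121) in the S animals, so a rise stays open too.

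With the mean of each title series removed, 20 probe sets parted the animals by a gap of over 1 log2 unit with at least 4 animals on each side, and 8 of these had no gene symbol. IRAK1 had the widest gap, 4.23. On its first probe set 6 animals lay between 12.25 and 13.34 and 14 between 6.20 and 7.46, and on another probe set the same 6 lay lower, between 6.69 and 8.0, against 8.68 to 9.74 in the 14. PRSS2 (2.08), RSPO3 (1.31), XDH (1.20 and 1.05 on its 2 probe sets), BOLA-DQB1 (1.15) and PCBD1 (1.06) had gaps as well.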
